A study of Oryza sativa with 8 samples.

How the data were processed

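The series measured messenger RNA levels with Affymetrix rice arrays in the aerial tissue of 14 day old rice plants. M202 is a japonica rice cultivar that does not survive long submergence. M202(Sub1) is M202 into which the SUB1 region of a tolerant rice was introgressed, and the labels give it as carrying the submergence tolerance gene Sub1A. Per the labels' protocols, plants grown in soil in a greenhouse were put completely under water at 14 days of age, and aerial tissue was harvested after 24 h. Total RNA was labelled with biotin by the manufacturer's one-cycle protocol, per the labels' protocols.

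The 8 arrays fall into 4 groups of 2, M202 and M202(Sub1), each non-submerged and submerged. The groups and replicate numbers were taken from the sample labels. The series' design text calls the replicates independent and biological, without saying what separated them, so a p-value measures the spread between these samples. The titles place the non-submerged arrays at day 0 and the submerged arrays at day 1, so 1 day of age goes together with submergence in every submergence comparison. The time of day at which non-submerged plants were harvested is not given in the sources used here, so it may also differ.

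The deposited values are log2 expression levels, 1 per probe set and array, made by the authors. The submitters' processing notes name GCRMA and MAS5 without a role, an order or a version. The deposited log2 values ran from 2.22 to 16.9, with a floor of 2.22 shared by all 8 arrays, and held no detection calls, a scale that GCRMA gives and MAS5 does not. Whether the 8 arrays were normalized in 1 run, and which genome build stood behind the array, is not given in the sources used here. Between 37.3% and 38.8% of the values of each array were at the floor. The array medians lay between 2.302 and 2.325, and the array 75th percentiles between 7.209 and 7.36. Arrays have no read depth, and their number, 2 per group, limits the precision.

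The table held 57381 probe sets with 0 missing values. The 123 control probe sets were kept out of the tests and used as a separate check. Of the 57258 others, 22436 were paired with exactly 1 gene by the platform annotation, 95 with several genes, and 34727 were not listed with a gene there. The 17905 genes so named were all matched by gene identifier in the RefSeq gene table of assembly ASM3414082v1, which gave symbols for 2458 of them. That table was used only for names, chromosomes and the order of neighbouring genes, and none of its coordinates are printed. A probe set with several genes was never named. The annotation used here pairs no probe set with SUB1A, SUB1B, SUB1C, ADH1, ERF66 or ERF67 by name, and these genes are not analysed here. Gene symbols are those of the table. RAmy3D appears there as AMY1.3, and the symbols HSF25 and HSFA2D belong to entries that also carry the names ARD1 and ARD2 of an unrelated enzyme, so no function is given for them.

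Probe sets were tested when their mean over the 8 arrays was at or above the 40th percentile, a log2 value of 2.23, which left 34355. The filter value lies close to the floor, so many tested probe sets were near the floor in some group. Group means within 0.1 of the floor are named in the text, because a fold against them is limited by the floor. Arrays held at a floor also show no spread, which lowers the SE and adjusted p of such probe sets. Single probe sets also had floors of their own, where both arrays of a group lay within 0.005 of the probe set's lowest value and that value was below 3. Among called probe sets 1.8% had such a group for submergence in M202, 2.2% in M202(Sub1), 8.5% for genotype in non-submerged plants, 2% for genotype in submerged plants and 5.3% for the interaction. This was looked at after the data were seen, and the named genes concerned are pointed out. The values were used as deposited. limma 3.58.1 in R 4.3.3 was fitted with 1 coefficient per group to all 8 arrays (lmFit), with empirical Bayes moderation and an intensity trend (eBayes). The fit left 4 residual degrees of freedom, and the prior added 0.99. The 5 contrasts were tested with Benjamini-Hochberg adjustment, and a call is an adjusted p below 0.05. The contrasts were submergence in M202, submergence in M202(Sub1), genotype in non-submerged plants, genotype in submerged plants, and the interaction, which is the submergence effect in M202(Sub1) minus that in M202. Tables were prepared with Python 3.11.15 and pandas 2.3.3. A fold of 2 or more was counted beside each total. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333, so none was run.

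The tests, the 31 gene lists, the rule for the genes named and the alternatives were chosen before the data were examined. The lists had been written as words of gene descriptions and as locus numbers. Because the gene table gave symbols only, they were translated into symbol families after the symbols had been seen and before any test was run. The lists were anaerobic fermentation, starch and sucrose breakdown, glycolysis, photosystems and light harvesting, Calvin cycle, chlorophyll synthesis, chlorophyll breakdown, expansins and cell wall loosening, cellulose synthesis, AP2/ERF transcription factors, ethylene synthesis and signalling, gibberellin, abscisic acid, dehydrins and LEA proteins, jasmonate, auxin response, heat shock proteins, antioxidant enzymes, glutathione S-transferases, haemoglobins, WRKY transcription factors, pathogenesis-related proteins, aquaporins, nitrate and ammonium assimilation, cytosolic ribosomal proteins, histones, DNA replication and cell cycle, circadian clock, lignin and phenylpropanoid, root markers and seed markers. The cellulose synthesis list holds cellulose synthase-like (CSL) genes beside cellulose synthase (CESA) genes, so it does not stand for cellulose synthesis alone. Each gene was represented by its probe set with the highest mean. The 26 lists with at least 5 measured genes were tested with camera (preset correlation 0.01) and adjusted over the lists within a contrast. The other 5 were described by counts only. With a correlation estimated per list, no list was called in any contrast, and the adjusted p of each called list under that setting is given beside it. fry, which tests whether the genes of a list move on balance in 1 direction, was run as an alternative.

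For each contrast the genes named were, first, the 10 largest rises and the 10 largest falls among called probe sets with 1 symbol whose 2 arrays of one group lay above both arrays of the other. For the interaction, the submergence differences of both genotypes had to lie outside each other's replicate range. Second came up to 4 members of each list with the smallest adjusted p. Last came a fixed set of fermentation, sucrose synthase, amylase and DELLA genes, whatever their value. ABA8OX2 lay outside this rule and was chosen after its values were seen. Some were left out for length, among them symbols whose product is unclear.

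The share of genotype calls on chromosome 9, which carries the SUB1 locus, was compared with its share of the genes tested by Fisher's exact test, two-sided. Calls per length of chromosome 9 had been planned, but with no genome build named for the array they were counted per stretch of 50 neighbouring tested genes instead. Calls of both submergence contrasts, which share no array, were compared by Fisher's exact test and by correlation across probe sets, which are not independent replicates.

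The fit was tested on simulated data made from the means and spreads of these 34355 probe sets, with 200 changed probe sets drawn from those with a mean above 5, so the shares below do not cover dim probe sets. For submergence in M202 it recovered 57% of the 2-fold and 89% of the 4-fold changes, and for submergence in M202(Sub1) 61% and 91%. For genotype in non-submerged plants the shares were 56% and 91%, for genotype in submerged plants 64% and 94%, and for the interaction 35% and 79%. Every recovered change had the right sign, and false calls made up 3.4% to 7% of all calls. These shares hold for 200 changed probe sets, fewer than were called in any contrast, so recovery in the data may differ. The list test, run on 30 simulated lists of 15 genes for the genotype contrast in submerged plants, called all 5 lists raised by 0.5 on the log2 scale and 1 unchanged list. The simulated probe sets varied independently, so this does not test the list calls against correlation between genes.

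Alternatives tried were quantile normalization, centring on the 75th percentile, raising low values to the 20th percentile, no filter, a filter at the 60th percentile, eBayes without a trend or with a robust prior, fits to only the 4 arrays of a contrast, the replicate number as a block, leaving out each array in turn, 1 probe set per gene, leaving out probe sets of shared probes, a required fold of 2, and other list tests. Centring on the poly(A) spike-in controls was added after the control probe sets had been seen.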

Results

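Transcript levels were measured in aerial tissue of M202 and M202(Sub1) rice, in non-submerged plants and after 24 h of complete submergence, with 2 arrays in each of the 4 groups. The values are deposited log2 signals of 34355 probe sets. Arrays of the same group correlated at r = 0.9974 to 0.9982 across probe sets. All changes below are differences of log2 group means with their standard error (SE) from the limma fit, n = 2 arrays per group, with limma's adjusted p. They are relative to the scale of the deposited values, on which the median probe set changed by 0 in both submergence contrasts. When the arrays were centred instead on the poly(A) spike-ins, bacterial transcripts added during labelling, the median moved by -0.19 in M202 and -0.40 in M202(Sub1).

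The first comparison asked what submergence changed in M202, which lacks Sub1A. Submergence was followed by a strong rise of the fermentation genes. Adh2, an alcohol dehydrogenase of ethanol fermentation, rose by 6.04 ± 0.06 (log2, SE, n = 2 per group; adjusted p = 1.22e-06). PDC1 and PDC2, pyruvate decarboxylases that start ethanol fermentation, rose by 3.06 ± 0.12 and 2.08 ± 0.03. All 3 measured members of the anaerobic fermentation list rose, also when adjusted over the list alone. Adh2 had the same value, 2.44, on all 4 non-submerged arrays, the lowest that its probe set gave, and PDC1 was within 0.1 of the common floor in non-submerged M202. The folds of both genes are thus limited by a floor. The equal values of Adh2 also lower its SE and adjusted p.

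The carbohydrate lists held called genes in both directions in M202. Of 15 measured genes of starch and sucrose breakdown, 5 rose, 4 fell and 6 were not called, and 9 passed when adjusted over the list alone (camera adjusted p = 0.925), with a median of 0.07 that was -0.12 after centring on the poly(A) spike-ins. SUS4, a sucrose synthase, rose by 3.31 ± 0.03 and the alpha-amylase AMY1.5 by 3.17 ± 0.10, while the cell wall invertase CIN1 fell by 1.55 ± 0.06. SUS1 had a value of -0.11 ± 0.05 (limma adjusted p = 0.158). Sus2, another sucrose synthase, had 11.79 and 11.69 on the non-submerged arrays and 12.95 and 13.09 on the submerged ones. AMY1.3, listed also as RAmy3D, stayed near the floor with 0.20 ± 0.10 (limma adjusted p = 0.173). Of 15 glycolysis genes 4 rose, 3 fell and 8 were not called, and 8 passed when adjusted over the list alone (camera adjusted p = 0.925). HXK6, a hexokinase, rose by 3.50 ± 0.26 and AldC-1, a cytosolic aldolase, by 1.52 ± 0.03, while GPI-B, a phosphoglucose isomerase, fell by 3.11 ± 0.10. Outside the lists, ICL, the isocitrate lyase of the glyoxylate cycle, rose by 9.36 ± 0.36. BURP16, which encodes a BURP-domain protein, rose by 13.45 from 2.48, the lowest value of its probe set, held on all 4 non-submerged arrays, so this fold is limited by that floor.

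TIP1-2, a tonoplast aquaporin, fell by 9.83 ± 0.25 and PIP2-4, a plasma membrane aquaporin, by 5.70 ± 0.28. Aquaporin genes moved both ways, since 11 of 21 fell, 7 rose and 3 were not called, with 19 passing when adjusted over the list alone (camera adjusted p = 0.155). All 6 measured dehydrin and LEA genes fell, 6 also when adjusted over the list alone (camera adjusted p = 0.0105), and with an estimated correlation the adjusted p was 0.493. RAB21 fell by 4.74 ± 0.12 and Dhn1 by 4.17 ± 0.10, both dehydrins that respond to drought and abscisic acid. In the abscisic acid list 8 of 11 genes fell, 1 rose and 2 were not called, with 9 passing when adjusted over the list alone (camera adjusted p = 0.0263). That list had an adjusted p of 0.493 with an estimated correlation. ZEP, the zeaxanthin epoxidase of abscisic acid synthesis, fell by 2.71 ± 0.05, and ABA8OX1, which breaks abscisic acid down, rose by 3.42 ± 0.15, while ABA8OX2, an enzyme of the same kind, fell by 2.85 ± 0.15. PP2C30, a protein phosphatase 2C, fell by 5.74 ± 0.28.

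In the chlorophyll synthesis list 7 of 8 genes fell, 0 rose and 1 was not called, with 7 passing when adjusted over the list alone (camera adjusted p = 0.0273). Its adjusted p was 0.493 with an estimated correlation and 0.0524 without replicate 1 of non-submerged M202. CHLI, a subunit of magnesium chelatase, fell by 2.90 ± 0.16 and PORB, a protochlorophyllide reductase, by 0.60 ± 0.04. Of 7 photosystem genes 5 fell, 0 rose and 2 were not called, with 5 passing when adjusted over the list alone (camera adjusted p = 0.138). Of 4 chlorophyll breakdown genes, RCCR1 rose by 3.08 ± 0.07 and SGR, the stay-green gene that starts chlorophyll degradation, by 1.57 ± 0.07, NOL fell by 0.27 ± 0.04 and 1 was not called, with 3 passing when adjusted over the list alone. Among 18 antioxidant enzyme genes 12 fell, 3 rose and 3 were not called, with 15 passing when adjusted over the list alone (camera adjusted p = 0.0263), and with an estimated correlation the adjusted p was 0.493. APX7, an ascorbate peroxidase, fell by 3.19 ± 0.09, and the catalase CAT-B rose by 1.18 ± 0.05.

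In M202 ETR2, an ethylene receptor, rose by 3.07 ± 0.10, and 4 of 9 ethylene genes rose, 1 fell and 4 were not called, with 5 passing when adjusted over the list alone (camera adjusted p = 0.155). In the gibberellin list 5 of 10 genes rose, 2 fell and 3 were not called, with 7 passing when adjusted over the list alone (camera adjusted p = 0.214). KAO and GA20OX3, which act in gibberellin synthesis, rose by 3.35 ± 0.11 and 3.15 ± 0.11. SLR1, the DELLA repressor of gibberellin response, had a value of 0.07 ± 0.11 (limma adjusted p = 0.709). EXLA1, an expansin-like gene, rose by 2.61 ± 0.06, the expansin EXPB7 rose by 2.82 ± 0.12 and EXP1 fell by 2.03 ± 0.09. Of 21 expansin genes 9 fell, 4 rose and 8 were not called, with 14 passing when adjusted over the list alone (camera adjusted p = 0.277). In total, limma called 14738 probe sets, 7879 higher and 6859 lower after submergence. A fold of 2 or more was reached by 3197 of the higher and 3210 of the lower ones. Higher calls made up 53.5% of the total, and 33.3% after centring on the poly(A) spike-ins.

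The second comparison asked the same of M202(Sub1), which carries Sub1A. The fermentation genes again rose, Adh2 by 8.93 ± 0.06 (log2, SE, n = 2 per group; limma adjusted p = 4.55e-07), PDC1 by 8.25 ± 0.12 and PDC2 by 3.59 ± 0.03, and all 3 passed when adjusted over the list alone. The fold of Adh2 is again limited by the floor of its probe set. HSP26.7, a small heat shock protein, rose by 9.86 ± 0.05 from a mean within 0.1 of the floor, so this fold is limited by the floor. Its probe set gave its lowest value, 2.25, on 6 of the 8 arrays, which also makes its SE small. TIP1-2 fell by 10.20 ± 0.25, and PMEI8, an inhibitor of pectin methylesterase, fell by 6.32 ± 0.10.

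In M202(Sub1) glycolysis genes had 7 rises, 2 falls and 6 without a call among 15, with 11 passing when adjusted over the list alone (camera adjusted p = 0.248), and a median of 0.25 that was -0.14 after centring on the poly(A) spike-ins. GAPC3, a cytosolic glyceraldehyde phosphate dehydrogenase, rose by 3.27 ± 0.09, AldC-1 by 2.86 ± 0.03 and the enolase Eno1 by 2.05 ± 0.08. In starch and sucrose breakdown 4 of 15 genes rose, 5 fell and 6 were not called, with 10 passing when adjusted over the list alone (camera adjusted p = 0.774), a median of -0.09 and a mean of 0.24. SUS4 rose by 3.50 ± 0.03, and SUS1 fell by 0.85 ± 0.05. Sus2 had 11.68 and 11.75 on the non-submerged arrays and 12.88 and 12.84 on the submerged ones.

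Chlorophyll synthesis genes fell in M202(Sub1), with 7 of 8 lower, 0 higher and 1 not called, and 7 passing when adjusted over the list alone (camera adjusted p = 0.0215). With an estimated correlation the adjusted p was 0.47. CHLI fell by 3.09 ± 0.16, PORA by 1.31 ± 0.04 and CHLH by 1.19 ± 0.06. The photosystem list had all 7 genes lower, 7 also when adjusted over the list alone, and the list itself missed the threshold (camera adjusted p = 0.0502). PSB28 fell by 1.71 ± 0.08. In the chlorophyll breakdown list RCCR1 rose by 2.02 ± 0.07, while NOL and NYC1, which act in chlorophyll b degradation, fell by 0.98 ± 0.04 and 0.67 ± 0.14, and NYC1 was not called without replicate 1 of either M202(Sub1) group (limma adjusted p = 0.053 and 0.0667). SGR had a value of 0.11 ± 0.07 (limma adjusted p = 0.284), and 3 of the 4 passed when adjusted over the list alone. Of 18 antioxidant genes 14 fell and 4 rose, and 18 passed when adjusted over the list alone (camera adjusted p = 0.0229), and with an estimated correlation the adjusted p was 0.47. PRXIIE-2, a peroxiredoxin, fell by 2.94 ± 0.08.

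Dehydrin and LEA genes had 4 falls, 0 rises and 2 without a call among 6 in M202(Sub1), with 5 passing when adjusted over the list alone (camera adjusted p = 0.0535). Dhn1 fell by 5.17 ± 0.10 and RAB21 by 3.01 ± 0.12. In the abscisic acid list 7 of 11 genes fell, 2 rose and 2 were not called, with 10 passing when adjusted over the list alone (camera adjusted p = 0.107). ABA8OX1 rose by 4.87 ± 0.15, while ABA8OX2 fell by 3.79 ± 0.15 and OsPP2C09, a protein phosphatase 2C, by 4.77 ± 0.17. In the gibberellin list 6 of 10 genes rose, 1 fell and 3 were not called, with 8 passing when adjusted over the list alone (camera adjusted p = 0.194). GA20OX2 rose by 2.62 ± 0.11, and the receptor gene gid1 by 1.97 ± 0.08. SLR1 rose by 0.38 ± 0.11 (limma adjusted p = 0.0328), but its value was -0.01 after centring on the poly(A) spike-ins and it was not called without 6 of the 8 arrays (limma adjusted p = 0.0584 to 0.148). SLRL1, a related repressor, had a value of 1.10 ± 0.53 (limma adjusted p = 0.161). Among 21 expansin genes 10 fell, 4 rose and 7 were not called, with 16 passing when adjusted over the list alone (camera adjusted p = 0.105). EXP1 fell by 2.44 ± 0.09, EXP2 by 2.17 ± 0.06 and EXPB3 by 1.81 ± 0.04. In total, limma called 16808 probe sets, 9517 higher and 7291 lower. A fold of 2 or more was reached by 4186 and 3881 of them. Higher calls made up 56.6% of the total, and 23.4% after centring on the poly(A) spike-ins.

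The responses of the genotypes were largely made of the same probe sets. In both, 6861 probe sets were called higher, where 2183 would be shared by independent lists (Fisher's exact test, odds ratio 60.4). Likewise, 5710 were called lower in both, against 1456 (odds ratio 81.3). Both sets of calls use the same estimate of spread from 1 fit, so the lists were not fully independent to begin with. Only 96 probe sets were called higher in M202 and lower in M202(Sub1), and 88 the reverse. Across the 34355 probe sets, which are not independent replicates, the log2 changes correlated with r = 0.929 and rho = 0.851, with a covariance of 1.465. BURP16 rose by 13.20 in M202(Sub1), again from 2.48 and limited by that floor, and by 13.45 in M202. The nitrate reductase gene NIA1 fell by 4.54 ± 0.04 in M202 and by 4.12 ± 0.04 in M202(Sub1).

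**Figure D1:**
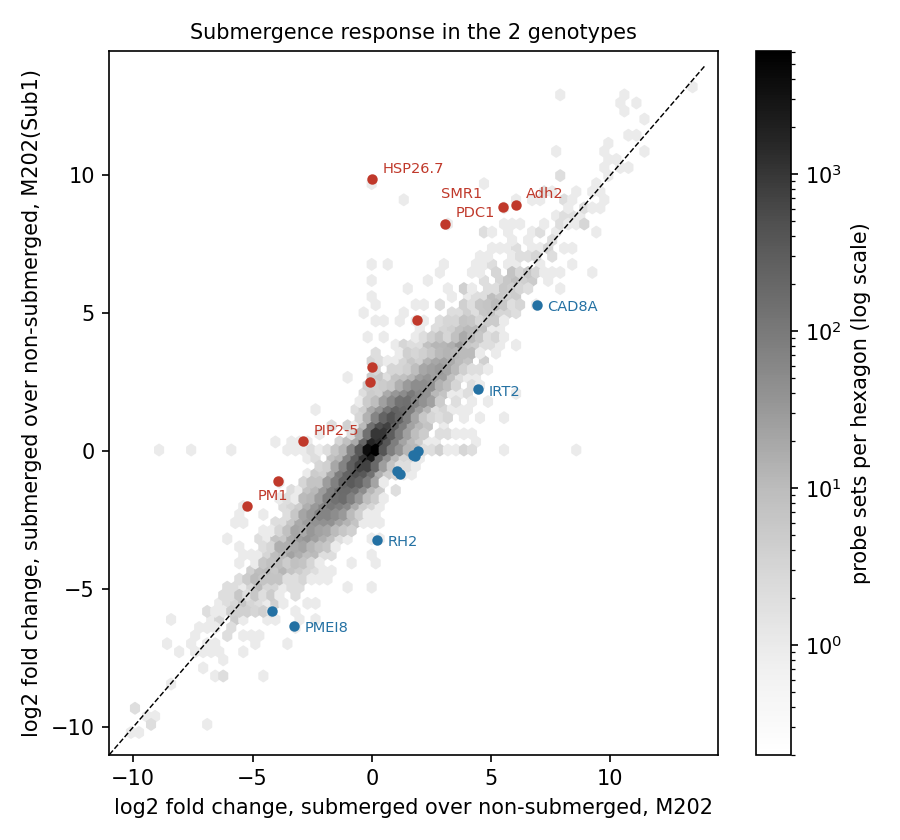
The log2 change after submergence in M202 (horizontal axis) is set against that in M202(Sub1) (vertical axis) for 34355 probe sets, drawn as hexagons shaded by the number of probe sets on a log scale, with a dashed line of equal change. Red and blue points are the 10 named genes with the largest positive and the 10 with the largest negative interaction, such as HSP26.7 at 0.00 and 9.86 and RH2 below the line.

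The third comparison asked whether the response itself differed, by testing the interaction. Fermentation genes rose more in M202(Sub1). The extra rise was 5.19 ± 0.16 for PDC1 (log2, SE, n = 2 per group; limma adjusted p = 0.000436), 2.89 ± 0.08 for Adh2 and 1.51 ± 0.05 for PDC2, and all 3 genes of the list passed when adjusted over the list alone. In non-submerged plants Adh2 was at the floor of its probe set and PDC1 near the common floor. The size of their extra rise is thus limited, which does not hold for PDC2. HSP26.7 had the largest interaction of the named genes, 9.86 ± 0.07, since it was within 0.1 of the floor in the other 3 groups.

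Glycolysis genes also responded more positively in M202(Sub1), with 7 of 15 higher, 0 lower and 8 not called, and 9 passing when adjusted over the list alone (camera adjusted p = 0.0206). With an estimated correlation the adjusted p was 0.39, and it was 0.0579 without replicate 2 of non-submerged M202 and 0.0553 without replicate 1 of non-submerged M202(Sub1). The interaction was 1.34 ± 0.04 for AldC-1, 1.22 ± 0.13 for GAPC3 and 0.98 ± 0.11 for Eno1. SUS1 went the other way, with -0.74 ± 0.07. Pathogenesis-related genes had 5 of 14 higher, 0 lower and 9 not called, with 5 passing when adjusted over the list alone (camera adjusted p = 0.0438), and with an estimated correlation the adjusted p was 0.39. This list was not called without either array of non-submerged M202, replicate 1 of submerged M202, replicate 1 of non-submerged M202(Sub1) or replicate 2 of submerged M202(Sub1) (camera adjusted p = 0.0613 to 0.0899). Among its genes were the chitinases Cht2 with 2.21 ± 0.09 and Cht11 with 1.78 ± 0.13. Cht2 went from 9.43 and 9.39 to 7.03 and 7.22 in M202. In M202(Sub1) it went from 9.21 and 9.19 to 9.13 and 9.11, so its value comes from the fall in M202. Cht11 had 7.46 and 7.66 in non-submerged M202(Sub1) against 9.05 and 8.97 in M202. After submergence it had 10.24 and 10.39 against 9.93 and 10.04, so its value comes largely from its lower start. Chib3H-a had 2.06 ± 0.08, limited by the floor, since its means in the other 3 groups were within 0.1 of it.

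Expansin and lignin genes had lower interaction values. Of 21 expansin genes 5 were lower, 0 higher and 16 not called, with 7 passing when adjusted over the list alone (camera adjusted p = 0.00348), and with an estimated correlation the adjusted p was 0.361. EXP2 had -1.61 ± 0.09, EXPB11 -0.94 ± 0.15 and EXPB3 -0.90 ± 0.06, and EXPB11 was not called without 5 of the 8 arrays (limma adjusted p = 0.05 to 0.0675). Of 22 lignin and phenylpropanoid genes 9 were lower, 0 higher and 13 not called, with 9 passing when adjusted over the list alone (camera adjusted p = 0.00602). The adjusted p was 0.615 with an estimated correlation and 0.0553 without replicate 1 of non-submerged M202(Sub1). The laccases LAC4 and LAC10 had -1.55 ± 0.12 and -1.14 ± 0.09, and the cinnamyl alcohol dehydrogenases CAD8A and CAD3 had -1.63 ± 0.22 and -1.07 ± 0.09. In the cellulose synthesis list, which holds CESA and CSL genes, 3 of 27 were higher, 4 lower and 20 not called. When adjusted over the list alone 7 passed (camera adjusted p = 0.511). PMEI8 had -3.08 ± 0.14.

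Of 4 chlorophyll breakdown genes 3 had a lower interaction value and 1 was not called, with 4 passing when adjusted over the list alone. The rise of RCCR1 was smaller in M202(Sub1), with -1.06 ± 0.10, and SGR had -1.46 ± 0.10. NOL had -0.72 ± 0.06, as its fall was larger in M202(Sub1). Of 8 chlorophyll synthesis genes, 1 was lower, 0 higher and 7 not called, with 2 passing when adjusted over the list alone (camera adjusted p = 0.0539). PIP2-5, a plasma membrane aquaporin, fell by 2.88 ± 0.10 in M202 and had 0.35 in M202(Sub1) (limma adjusted p = 0.0397), with an interaction of 3.24 ± 0.15. That 0.35 is smaller than the shift of 0.40 that centring on the poly(A) spike-ins takes off in M202(Sub1). The phosphate transporter gene PHT3 had an interaction of 2.87 ± 0.07, and the iron transporter gene IRT2 -2.22 ± 0.21. In the abscisic acid list 3 of 11 genes were higher, 0 lower and 8 not called, with 5 passing when adjusted over the list alone (camera adjusted p = 0.729), and PP2C51, a protein phosphatase 2C, had 1.93 ± 0.09, with the other 3 groups within 0.1 of the floor. In the gibberellin list gid1 and GA20OX2 were higher by 0.65 ± 0.11 and 0.73 ± 0.15, and 8 of 10 genes were not called, with 2 passing when adjusted over the list alone (camera adjusted p = 0.774), and the list's median of 0.04 was -0.17 after centring on the poly(A) spike-ins. Without 6 and 7 of the 8 arrays gid1 and GA20OX2 were not called (limma adjusted p = 0.0572 to 0.0799 and 0.0621 to 0.126). SLR1 had an interaction of 0.32 ± 0.15 and SLRL1 of 0.75 ± 0.74, neither called (limma adjusted p = 0.274 and 0.559).

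**Figure D2:**
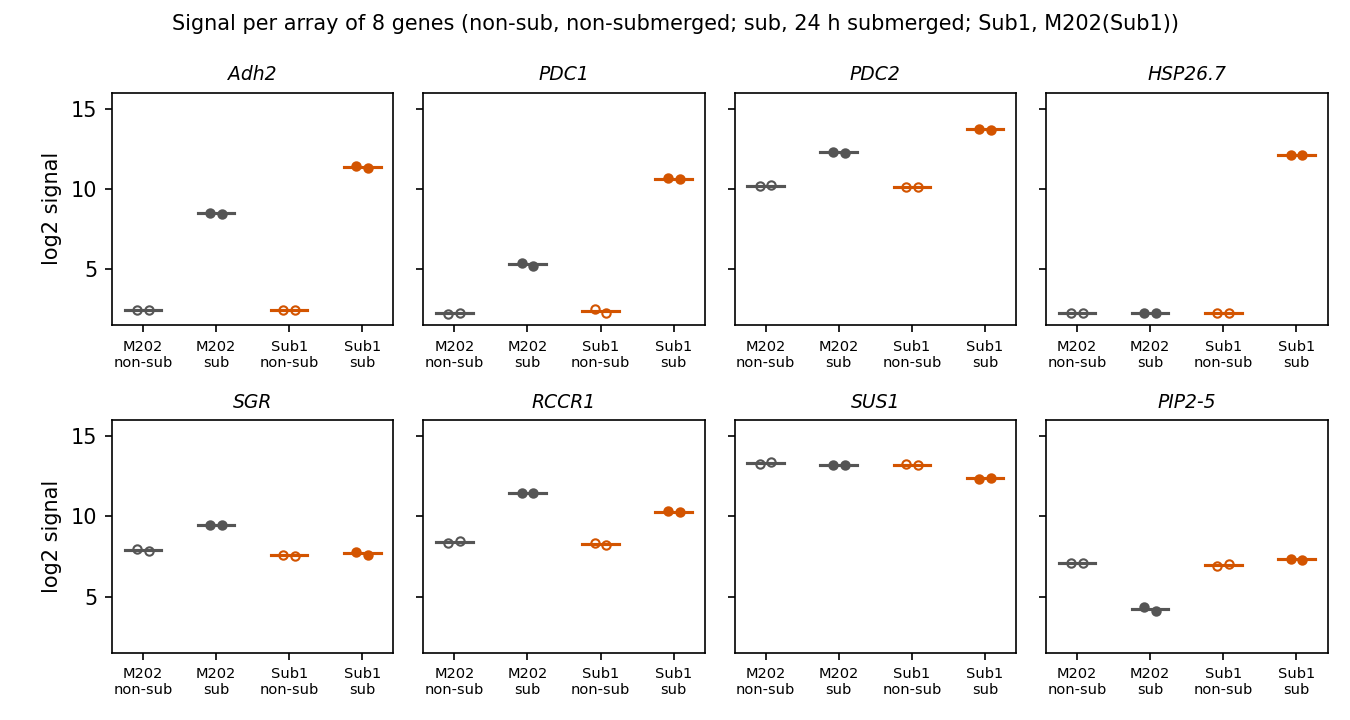
Each panel shows the log2 signal (vertical axis) of 1 gene on all 8 arrays, with points for arrays and bars for group means, grey for M202 and orange for M202(Sub1), open for non-submerged and filled for submerged plants. The mean of Adh2 was 2.44 in both non-submerged groups, 8.48 in submerged M202 and 11.36 in submerged M202(Sub1).

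In total, limma called 4223 probe sets for the interaction, 2186 positive and 2037 negative, and 481 and 527 of them reached a 2-fold difference. In 33.3% of the 4223 the rise was larger in M202(Sub1) and in 29.8% the fall was larger. The rise was smaller in 9.3% and the fall smaller in 8%, and 19.6% had opposite signs. These classes go by the sign of each estimated change, whether or not it was called. Among all tested probe sets, 184 were called in opposite directions by the 2 submergence contrasts. Without the filter on dim probe sets 2650 were called. Positive interactions made up 51.8% of the calls, and 19.7% after centring on the poly(A) spike-ins.

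The fourth comparison asked how M202(Sub1) differed from M202 before submergence. BURP17, another BURP-domain gene, was lower by 9.70 on the log2 scale, with means of 12.10 in M202 and 2.41 in M202(Sub1) (limma adjusted p = 2.11e-05). VDAC1, a mitochondrial outer membrane channel, had a difference of -4.66 ± 0.34 (SE, n = 2 per group). BURP17 on chromosome 11 and VDAC1 on chromosome 9 each lay in a stretch with 11 genotype calls. For both genes probe mismatches and lower expression cannot be told apart. The nicotianamine synthases NAS1 and NAS2, which make a metal chelator, had -3.55 ± 0.26 and -2.16 ± 0.07. Higher in M202(Sub1) were HATB by 2.13 ± 0.24 and PPT1, a phosphoenolpyruvate transporter, by 0.63 ± 0.06, and these were not called without 6 and 4 of the 8 arrays (limma adjusted p = 0.0572 to 0.0951 and 0.0519 to 0.0661).

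Dehydrin and LEA genes were lower in non-submerged M202(Sub1), with 2 of 6 called lower, 0 higher and 4 not called, and 3 passing when adjusted over the list alone (camera adjusted p = 0.000304). With an estimated correlation the adjusted p was 0.437. LEA19, a late embryogenesis abundant protein, had -3.26 ± 0.35 and RAB21 -1.67 ± 0.12. RAB16B had -1.40 ± 0.23 (limma adjusted p = 0.0739), and Dhn1 -0.17 ± 0.10 (limma adjusted p = 0.627). PM1, a membrane protein of the PM19 family, had -3.38 ± 0.20, and PP2C68, a protein phosphatase 2C in the abscisic acid list, -2.80 ± 0.27. PP2C68 lay in a stretch of chromosome 9 with 13 genotype calls, so probe mismatches and lower expression cannot be told apart for it. LEA19 was not called without 6 of the 8 arrays (limma adjusted p = 0.0526 to 0.0825) and PP2C68 without 3 of them (0.053 to 0.0641). Of that abscisic acid list 1 of 11 genes was lower, 0 higher and 10 not called, with 1 passing when adjusted over the list alone (camera adjusted p = 0.481).

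The haemoglobin genes NSHB1 and NSHB2, which encode proteins that bind oxygen and nitric oxide, were higher by 0.78 ± 0.09 and 0.74 ± 0.07, and both passed when adjusted over the list alone. NSHB1 was not called without 6 of the 8 arrays (limma adjusted p = 0.0504 to 0.0872) and NSHB2 without either array of submerged M202 (0.0538 and 0.0539). HSP24.1, a small heat shock protein, was higher by 0.76 ± 0.05, and 2 of 43 heat shock genes were higher, 0 lower and 41 not called, with 6 passing when adjusted over the list alone (camera adjusted p = 0.159). The chitinase Cht11 had -1.45 ± 0.09. None of the 3 fermentation genes, 0 also when adjusted over the list alone, was called (Adh2 0.00 ± 0.06, PDC1 0.15 ± 0.12, PDC2 -0.09 ± 0.03). Adh2 was at the lowest value of its probe set on all 4 non-submerged arrays, which sets its difference to 0, and PDC1 lay near the common floor with means of 2.24 and 2.39, so these values cannot show whether the 2 genes differed.

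In total, limma called 657 probe sets, 235 higher and 422 lower in M202(Sub1), and 83 and 221 of them reached a 2-fold difference. Higher calls made up 35.8% of the total, and 25.9% after centring on the poly(A) spike-ins. This count moved with single arrays, from 395 without the first submerged M202(Sub1) array and 396 without the second, to 1275 and 1107 without either non-submerged M202 array and 1769 and 1461 without either non-submerged M202(Sub1) array, and the share of higher calls ranged from 15.8% to 70.6%.

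The fifth comparison asked how the genotypes differed after submergence. PDC1 was higher in M202(Sub1) by 5.34 ± 0.12 (log2, SE, n = 2 per group; limma adjusted p = 4.4e-05), Adh2 by 2.89 ± 0.06 and PDC2 by 1.42 ± 0.03, and 3 of 3 fermentation genes passed when adjusted over the list alone. Glycolysis genes were higher, with 7 of 15 called higher, 1 lower and 7 not called, and 9 passing when adjusted over the list alone (camera adjusted p = 0.0462). Their median was 0.29 as deposited, and centring on the poly(A) spike-ins moves the median probe set of this comparison by -0.25. The adjusted p was 0.5 with an estimated correlation and 0.0525 to 0.0611 without 6 of the 8 arrays. AldC-1 was higher by 1.42 ± 0.03 and GAPC3 by 1.12 ± 0.09. SUS1 was lower, with -0.82 ± 0.05.

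Heat shock genes had 15 of 43 higher in submerged M202(Sub1), 2 lower and 26 not called, with 20 passing when adjusted over the list alone (camera adjusted p = 0.0462), and a median of 0.09 as deposited and -0.16 after centring on the poly(A) spike-ins. The adjusted p was 0.554 with an estimated correlation, and 0.0505 to 0.0735 without each of the 8 arrays in turn. HSP26.7 had a difference of 9.86 ± 0.05, with its fold and SE limited by the floor in submerged M202, and HSP18.0 of 1.13 ± 0.02. Auxin response genes had 15 of 52 higher, 5 lower and 32 not called, with 22 passing when adjusted over the list alone (camera adjusted p = 0.0482), and a median of 0.19 as deposited and -0.06 after centring on the poly(A) spike-ins. The adjusted p was 0.554 with an estimated correlation, and 0.0525 to 0.0735 without each array in turn. ARF9, an auxin response factor, was higher by 1.57 ± 0.04 and GH3.2, which conjugates auxin, by 1.86 ± 0.11. NSHB1 and NSHB2 were higher by 1.11 ± 0.09 and 0.94 ± 0.07, and both passed when adjusted over the list alone.

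Lignin and expansin genes were lower in submerged M202(Sub1). Of 22 lignin genes 10 were lower, 0 higher and 12 not called, with 10 passing when adjusted over the list alone (camera adjusted p = 0.00793), and with an estimated correlation the adjusted p was 0.554. LAC4 had -1.43 ± 0.09 and CAD3 -1.15 ± 0.06. Of 21 expansin genes 8 were lower, 0 higher and 13 not called, with 11 passing when adjusted over the list alone (camera adjusted p = 0.0357), and with an estimated correlation the adjusted p was 0.5. That of the expansins was 0.0672 without replicate 2 of submerged M202 and 0.0512 without replicate 1 of submerged M202(Sub1). EXP2 had -1.41 ± 0.06 and EXPB7 -0.98 ± 0.12. In the cellulose synthesis list of CESA and CSL genes 3 of 27 were higher, 5 lower and 19 not called. When adjusted over the list alone 8 passed (camera adjusted p = 0.454). Of 8 chlorophyll synthesis genes 2 were lower, 0 higher and 6 not called, with 2 passing when adjusted over the list alone (camera adjusted p = 0.128). All 4 chlorophyll breakdown genes were lower, 4 also when adjusted over the list alone, with SGR at -1.77 ± 0.07 and RCCR1 at -1.17 ± 0.07, though NYC1 was not called without replicate 1 of either submerged group (limma adjusted p = 0.056 and 0.0702). MT1B, a metallothionein, had -1.89 ± 0.09. The root silicon transporter gene Lsi1, the only measured root marker, had 0.20 ± 0.04 on submergence in M202, -0.56 ± 0.04 in M202(Sub1), and -0.68 ± 0.04 between the submerged groups. The seed marker list had 1 of 2 genes called higher on submergence in each genotype, GLUA-2, with 0.57 ± 0.08 and 0.42 ± 0.08. On the 8 arrays Lsi1 had 9.49 to 10.23 and GLUA-2 8.97 to 9.65, above the array 75th percentiles of 7.209 to 7.36. GLUB-5, the other seed marker measured, had 3.16 to 3.79. A difference in tissue make-up between the groups was not tested.

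In total, limma called 7123 probe sets in this comparison, 3638 higher and 3485 lower in M202(Sub1), and 482 and 694 of them reached a 2-fold difference. After centring on the poly(A) spike-ins 15784 were called, of which 10.2% were higher, against 51.1% as deposited. Fitted to only the 4 submerged arrays, 3000 were called, with 0 of the 3 lists called higher (glycolysis, heat shock, auxin) and 2 lists called lower. Leaving out each array in turn left 1 to 3 called lists in place of 5, with 0 called higher without 6 of the 8 arrays and 1 without replicate 2 of either submerged group. Of the probe sets called between the genotypes, 416 were called in both conditions, where 136 would be shared by independent lists, and 359 of them had the same sign. The 2 lists share the fit's estimate of spread and so are not fully independent.

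Genes that differed between non-submerged M202(Sub1) and M202 were not spread evenly over the genome. Of the 329 called genes 48, or 14.6%, lay on chromosome 9, which carries the SUB1 locus and 5.4% of the genes tested (Fisher's exact test, two-sided, odds ratio 3.12, p = 2.56e-10). Among them were HATB, VDAC1, PP2C68 and PPT1. Chromosome 12 held 60 of the called genes (18.2%, adjusted p = 3.8e-17 by Fisher's exact test over the 12 chromosomes), chromosome 11 held 40 (12.2%, adjusted p = 5.04e-08), with BURP17 among them, and chromosome 6 held 36 (10.9%, adjusted p = 0.0451). Fisher's exact test counts genes as independent, but called genes lay together. On chromosome 9, adjoining stretches of 50 tested genes held 10, 13 and 11 of them, so these p-values are too small. After submergence chromosome 9 held 281 of 4694 called genes, 6% (Fisher's exact test, p = 0.0311, adjusted p = 0.172 over the 12 chromosomes). Among called genes with a fold of 2 or more the share was 10.14% (Fisher's exact test, p = 7.4e-07). In the fit to only the 4 submerged arrays the share was 6.02% (Fisher's exact test, p = 0.18).

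**Figure D3:**
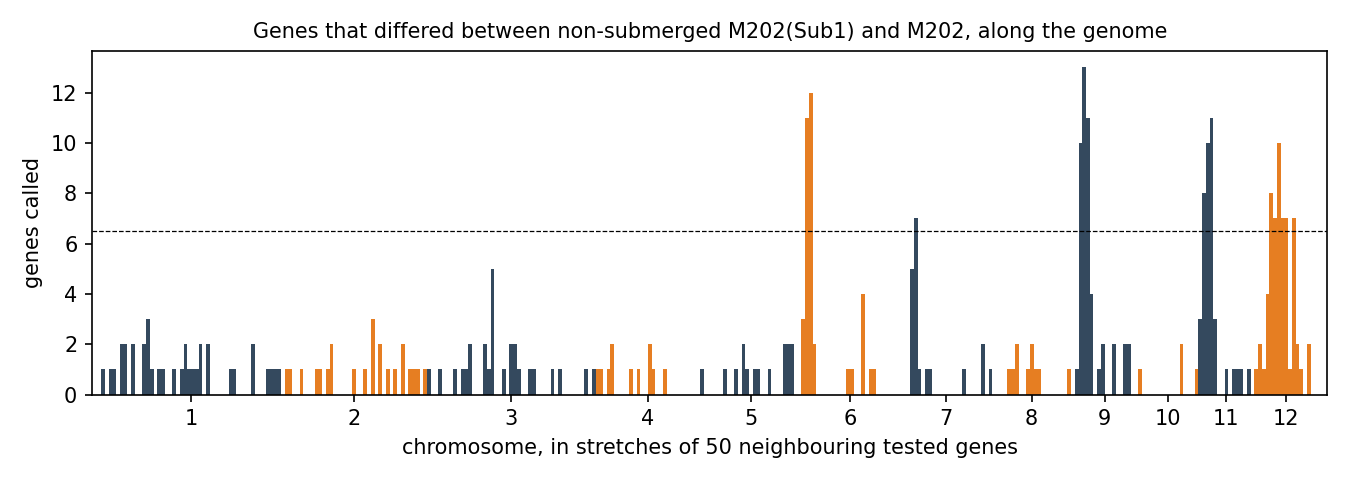
Bars give the number of genes called between non-submerged M202(Sub1) and M202 (vertical axis) in each stretch of 50 neighbouring tested genes (horizontal axis, chromosomes 1 to 12 in alternating colours), and bars above the dashed line hold 7 or more. The 15 stretches above the line lie on chromosomes 6, 7, 9, 11 and 12, with a highest count of 13 on chromosome 9.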

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

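The permutation test of the stretches, the test of the direction of calls within them, the test of single arrays for the dehydrin list, and the centring on the spike-ins were chosen after the result was seen.

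Genes called between non-submerged M202(Sub1) and M202 lay together: 15 of 325 stretches of 50 neighbouring genes held 7 or more calls, and with them 139 of the 329 calls. In 10000 permutations of the calls over the genes the highest number of such stretches was 1, so chance placing is argued against (permutation p = 0.0001, the smallest they can give). In these stretches 75.5% of the calls were also called with the same sign in the submerged groups, against 40.5% of the calls elsewhere. The submerged groups hold other arrays, but both sets of calls use the same estimate of spread from 1 fit, so they are not independent. If the probes match M202, mismatches to donor sequence lower a signal, and 72.7% of the calls in the stretches were lower (exact 95% interval 64.5 to 79.9) against 58.4% elsewhere, a difference in the direction that mismatches give, while the 38 higher calls are not accounted for by them. For the calls that were lower, mismatches and lower expression cannot be told apart: 45.5% of them also had a called interaction, and the arrays that gave the calls also enter that test, so donor segments on chromosomes 6, 7, 9, 11 and 12 that may act through sequence, expression or both are a hypothesis.

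The interaction was called for 4223 probe sets by limma, and 63.1% of them were larger changes of the same sign in M202(Sub1). Differences in the distribution of values between arrays are argued against as the whole cause, since the share was 63.5% after quantile normalization. It was 66.1% after centring on the poly(A) spike-ins, which cannot decide whether less plant RNA beside the spike-ins gave the pattern. That centring moves the median response by -0.19 in M202 and -0.40 in M202(Sub1), and so enlarges falls in M202(Sub1) by itself. Only 19.7% of the interaction calls were positive under it. As the whole cause of the interaction calls, a uniform stretch of all changes in M202(Sub1) is argued against too. With the M202 response multiplied by the slope of 1.106 between the responses, 3530 probe sets passed, 83.6% of the interaction count, and 3192 were in both. The share of larger changes in M202(Sub1) was not taken again after this step, so the test cannot decide whether a stretch gave the 63.1%. A larger response of M202(Sub1) at 24 h is thus a hypothesis, while a difference in the timing of the response between the genotypes may give the same picture and was not tested.

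Dehydrin and LEA genes were lower as a list in non-submerged M202(Sub1), with 2 of 6 members called, of which LEA19 was not called without 6 of the 8 arrays (adjusted p = 0.0526 to 0.0825), and Dhn1 at -0.17 (limma adjusted p = 0.627), and the list's adjusted p was 0.437 with an estimated correlation. Probe mismatches in the stretches with 7 or more calls are argued against, as 0 of the 6 members lay in such a stretch. Shorter donor segments and mismatches in single genes are not covered, since only 139 of the 329 calls lay in these stretches. A single array is argued against, as the list's highest adjusted p in limma's camera test was 0.0102 without each array in turn. RAB16B, RAB16C, RAB16D and RAB21 are neighbours on chromosome 11 and may share a local cause, so the list holds fewer independent members than genes. A difference in the water status of the non-submerged plants was not tested.

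Other results for which the submergence effect differed between the genotypes are given here as log2 values, by camera for lists and by limma's interaction test for genes. The mean interaction was -0.37 for the expansin list, -0.38 for the lignin list, 0.43 for the glycolysis list and 0.77 for the pathogenesis-related list. With an estimated correlation their adjusted p was 0.361, 0.615, 0.39 and 0.39. Without 1 array the lignin list was not called (adjusted p = 0.0553), nor were glycolysis without 2 (0.0553 and 0.0579) and the pathogenesis-related list without 5 (0.0613 to 0.0899). Among genes with positive interactions were HSP26.7 (9.86), PDC1 (5.19), SMR1 (3.35), PM1 (3.24), PIP2-5 (3.24), GRF7 (3.04), Adh2 (2.89), PHT3 (2.87), LEA19 (2.85) and HIRL2 (2.57), and both probe sets of PDC2 (1.55 and 1.51). LEA19 was not called without 6 of the 8 arrays (limma adjusted p = 0.0621 to 0.0868). It was within 0.1 of the floor in submerged M202(Sub1), and PDC1 in non-submerged M202. GRF7 and Adh2 were at the lowest value of their probe sets on all 4 non-submerged arrays, which limits their folds. PM1 had 8.32 and 8.20 in non-submerged M202, 5.10 and 4.67 in non-submerged M202(Sub1), and 2.69 to 3.09 in both submerged groups. Its interaction thus comes from its lower start in M202(Sub1). GRF7, HIRL2, BURP17 and WNK3 lay in stretches with 7 or more genotype calls. Negative interactions were those of RH2 (-3.46), PMEI8 (-3.08), IRT2 (-2.22), BURP17 (-2.01), OSPIN10a (-2.00), MODD (-1.93), CIPK16 (-1.87), WNK3 (-1.77), CAD8A (-1.63) and BURP2 (-1.63), and of both probe sets of SUS1 (-0.74 and -0.89). OSPIN10a and BURP2 were each not called without 6 of the 8 arrays (limma adjusted p = 0.0543 to 0.109 and 0.0628 to 0.0733), nor was MODD without either array of non-submerged M202 or replicate 2 of submerged M202(Sub1) (0.0506 to 0.0569). BURP17 was at the floor in submerged M202(Sub1).

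Control probe sets, which the comparisons did not use, also moved. The 36 poly(A) spike-in probe sets were 0.40 higher (log2) on the submerged than on the non-submerged M202(Sub1) arrays, while arrays of the same group differed by at most 0.13, and in M202 they were 0.19 higher. The hybridization spike-ins were -0.71 on replicate 1 against replicate 2 of non-submerged M202. The probe sets for rice actin moved by -0.22 in M202 and -0.61 in M202(Sub1), those for cyclophilin by -0.46 and -0.86, for GAPDH by -0.42 and 0.02, and for ubiquitin by 0.07 and 0.22.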

How the results depend on the processing

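Centring on the poly(A) spike-ins was chosen after seeing the data. Fits without 1 array assume that the lone array of its group varies like the others. Raising low values to the 20th percentile changed nothing, since that percentile is the floor, and tests nothing. Signals at the floor limit what can be called among dim probe sets. Beyond the values here, counts of calls and chromosome 9 shares stayed within 1.5 times of the reported ones, which does not hold for single genes and lists, and the cause of each change was not tested unless fewer arrays, fewer probe sets or a stricter rule made it.

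A required fold of 2 left 6407 calls for submergence in M202, 8067 in M202(Sub1), 304 between non-submerged and 1176 between submerged genotypes, and 1008 interactions, and the chromosome 9 share of genotype calls after submergence was 10.14% (Fisher's exact test, p = 7.4e-07), against 5.99%. With 1 probe set per gene there were 11085 calls for submergence in M202(Sub1) and 367 between non-submerged genotypes. Fits to only the 4 arrays of a contrast gave 161 calls between non-submerged and 3000 between submerged genotypes, a chromosome 9 share of 6.02% after submergence, and 2 lists between submerged genotypes. Without the filter there were 2650 interactions and 1 list between submerged genotypes. Centring on the poly(A) spike-ins gave 27140 calls for submergence in M202(Sub1) and 15784 between submerged genotypes, and moved the share of higher calls from 53.5% to 33.3% in M202, 56.6% to 23.4% in M202(Sub1), 51.1% to 10.2% between submerged genotypes and 51.8% to 19.7% for the interaction. Between non-submerged genotypes that share was 15.8% to 70.6% without single arrays, against 35.8%. After quantile normalization CAB2R in M202 had 0.01, against -0.17, and 2 lists were called in M202.

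For M202(Sub1) submergence, 7 lists were called with the 60th percentile filter, 4 without a trend in eBayes, 4 with a robust prior and 1 after centring on the 75th percentile, against 2. The 60th percentile filter gave 2 lists between non-submerged genotypes. With a correlation estimated per list, 0 lists were called in each of the 5 contrasts. By fry 21 lists were called in M202, 25 in M202(Sub1), 16 between submerged genotypes and 13 for the interaction.

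Leaving out each array in turn gave 12974 to 14143 calls for submergence in M202, 15711 to 16347 in M202(Sub1), 395 to 1769 between non-submerged genotypes, 5192 to 6143 between submerged genotypes, 3096 to 4162 interactions and 10681 to 11751 shared submergence calls. Between non-submerged genotypes 1275 and 1107 were called without replicates 1 and 2 of non-submerged M202, 1769 and 1461 without those of non-submerged M202(Sub1), and 395 and 396 without those of submerged M202(Sub1). Called lists numbered 3 to 4 in M202, 2 to 4 in M202(Sub1) (4 without replicate 2 of non-submerged or replicate 1 of submerged M202(Sub1)), 1 to 2 between non-submerged genotypes (2 without replicate 2 of either non-submerged group), 1 to 3 between submerged genotypes (fewer than 5 without each of the 8 arrays), and 1 to 5 for the interaction (1 without replicate 1 of non-submerged M202(Sub1), 2 without replicate 2 of non-submerged M202). The chromosome 9 share ranged from 9.72% (without replicate 1 of non-submerged M202(Sub1)) to 15.69% in non-submerged plants, against 14.59%. In submerged plants it ranged from 5.77% to 6.47% (Fisher's exact test, p = 0.00262 to 0.198) with an unadjusted p above 0.05 without either array of non-submerged M202, submerged M202 or non-submerged M202(Sub1), and the reported share was itself no call over the 12 chromosomes (adjusted p = 0.172).

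Of 485 called values of named genes, 68 lost the call without at least 1 array and 417 kept it without each. Calls of named genes were also lost for 58 values in fits to only the 4 arrays, 35 without the filter, 18 with the replicate number as a block, 12 after quantile normalization, 11 after centring on the 75th percentile, 7 with the 60th percentile filter, 5 with a robust prior and 2 without a trend. Among lists, auxin response and heat shock between submerged genotypes lost the call without each array, glycolysis there without 6 (adjusted p = 0.0525 to 0.0611) and expansins without replicate 2 of submerged M202 and replicate 1 of submerged M202(Sub1) (0.0672 and 0.0512). Interaction calls were lost for pathogenesis-related genes without 5 arrays (0.0613 to 0.0899), glycolysis without 2 (0.0553 and 0.0579) and lignin without 1 (0.0553), and chlorophyll synthesis in M202 without 1 (0.0524).

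With the replicate number as a block, calls numbered 14587 in M202, 16707 in M202(Sub1), 462 and 6678 between non-submerged and submerged genotypes, 3636 for the interaction and 12500 shared, chromosome 9 shares were 16.67% and 6.13%, and called lists 4, 2, 1, 5 and 5. Same-numbered arrays had deviations correlated at 0.24 between submerged M202 and non-submerged M202(Sub1), and at 0.00 to 0.06 between other groups, across 22266 probe sets. The main fit took the numbers as names only. The 0.24 leaves open that these 2 groups share some variation.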

Other observations

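The centring on the poly(A) spike-ins was chosen after the data were seen, and the other tests here were not. Lists not described so far held single genes called after submergence (limma, log2 change ± SE, n = 2 per group). Haemoglobin genes rose in both genotypes, NSHB1 by 1.12 ± 0.09 in M202 and 1.45 ± 0.09 in M202(Sub1), NSHB2 by 1.08 ± 0.07 and 1.28 ± 0.07, and both passed when adjusted over the list alone. In the WRKY list 4 of 6 genes rose, 0 fell and 2 were not called in each genotype, with 4 passing in M202 and 5 in M202(Sub1) when adjusted over the list alone (camera adjusted p = 0.155 and 0.207), and WRKY24 rose by 3.06 ± 0.18 and 3.31 ± 0.18. In the nitrate and ammonium list 4 of 8 genes fell, 2 rose and 2 were not called in each genotype, with 6 passing when adjusted over the list alone (camera adjusted p = 0.205 and 0.207), and GLN2, the chloroplast glutamine synthetase, fell by 1.03 ± 0.03 and 1.42 ± 0.03. Of 27 CESA and CSL genes of the cellulose synthesis list 13 fell, 4 rose and 10 were not called in M202 (18 adjusted over the list alone, camera adjusted p = 0.155). In M202(Sub1) 16 fell, 6 rose and 5 were not called (22, camera adjusted p = 0.106). CESA1 fell by 1.03 ± 0.05 and 1.53 ± 0.05. Of 6 glutathione S-transferase genes 4 fell in M202 and 3 in M202(Sub1), 0 rose, and 4 and 3 passed when adjusted over the list alone (camera adjusted p = 0.143 and 0.135). Of 5 Calvin cycle genes 2 and 3 fell and 0 rose, with 2 and 3 passing when adjusted over the list alone (camera adjusted p = 0.274 and 0.187).

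For the remaining lists the called genes are given as higher and lower in M202, then in M202(Sub1), with the count adjusted over the list alone in parentheses. Of 43 heat shock genes 15 and 19 (34), then 18 and 16 (35) were called, and HSP18.1 fell by 5.61 ± 0.22 and 6.04 ± 0.22 while hsp17.9 rose by 3.57 ± 0.06 and 4.34 ± 0.06 (camera adjusted p = 0.511 and 0.957). Of 52 auxin genes 13 and 17 (35), then 25 and 14 (39) were called, with medians of 0.04 and 0.16 that were -0.15 and -0.23 after centring on the poly(A) spike-ins (camera adjusted p = 0.925 and 0.471). Of 30 jasmonate genes 11 and 11 (23), then 12 and 10 (22) were called, and the lipoxygenase gene CM-LOX2 rose by 3.23 ± 0.09 and 4.47 ± 0.09 (camera adjusted p = 0.994 and 0.957). Of 22 lignin genes 10 and 6 (17), then 5 and 7 (13) were called, and CAD8A rose by 6.93 ± 0.15 and 5.30 ± 0.15 (camera adjusted p = 0.925 and 0.358). Of 14 pathogenesis-related genes 3 and 5 (9), then 5 and 4 (9) were called, and PBZ1 fell by 2.54 ± 0.06 and 2.32 ± 0.06 (camera adjusted p = 0.875 and 0.957). Of 24 ribosomal protein genes 10 and 4 (15), then 14 and 5 (19) were called, with medians of 0.09 and 0.22 that were -0.10 and -0.17 after centring on the poly(A) spike-ins (camera adjusted p = 0.414 and 0.318). Of 25 DNA replication and cell cycle genes 4 and 2 (6), then 5 and 0 (4) were called, and the cyclin gene CYCD4-1 rose by 1.91 ± 0.31 in both genotypes (camera adjusted p = 0.925 and 0.863). Of 6 histone genes 2 and 2 (4), then 4 and 0 (4) were called (camera adjusted p = 0.925 and 0.276). Their median of 0.40 in M202(Sub1) is no larger than the shift of 0.40 that centring on the poly(A) spike-ins takes off. H2B.6 went from 0.33 to -0.06 there. Of 10 AP2/ERF genes 2 and 2 (4), then 3 and 2 (5) were called (camera adjusted p = 0.925 and 0.951). Of 6 clock genes 2 and 3 (5), then 3 and 3 (6) were called, and PRR37 fell by 1.38 ± 0.06 and 1.36 ± 0.06 (camera adjusted p = 0.727 and 0.957). The time of day of the non-submerged harvest is not given in the sources used here, so these changes hold any difference in it. The clock gene PRR1 rose by 0.37 ± 0.06 and 1.43 ± 0.06, with a called interaction of 1.06 ± 0.08.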
